A study of Mus musculus with 6 samples.

How the data were processed

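The series holds RNA-seq libraries of mouse epiblast stem cells, which are primed pluripotent cells derived from the epiblast of the embryo. Per the labels' protocols, the cells grew on inactivated mouse embryonic fibroblasts (feeder cells) in a medium with serum replacement, and the libraries were made with a stranded kit for polyadenylated RNA. The 6 samples fall into 2 groups of 3. Per the labels, both groups received FGF2 at 10 ng/mL, IWP2 at 5 µM and SB431542 at 2 µM. IWP2 blocks the secretion of Wnt proteins, and SB431542 inhibits type I receptors for Activin, Nodal and TGF-beta. Activin A was given at 20 ng/mL in the group with Activin A and was left out in the other. The treatment protocol is worded alike for all 6 samples and names Activin A in each. The growth factor label of the library without Activin A replicate 1 also names Activin A, against its title and its genotype label. The samples were grouped by the titles and genotype labels, and that library was left out in one of the alternatives.

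The deposited files give, for each of 133618 transcripts, an estimated count of reads and a TPM value. Per the file headers, each estimated count and TPM value stands in the columns that salmon writes, a tool that assigns reads to transcripts. The submitters' processing notes name salmon, DESeq2 and edgeR without versions. The deposited estimated counts need not be whole numbers and are not normalized. The deposited TPM values are scaled by transcript length and by library total. The genome build and annotation of the authors, and whether strand was used in the counting, are not given in the sources used here. Length minus effective length, rounded, was 249 bases for 99.2% of the 65015 transcripts longer than 1000 bases in the first library, and the effective lengths were the same in all 6 files.

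Transcripts were matched by identifier to GENCODE release M21 on GRCm38, the annotation used here for gene names and coordinates. Of the 133618 transcripts, 133399 matched with the version ignored, 131233 matched with the version, and 219 did not match. The unmatched transcripts held 0.140% ± 0.0066 of the reads (SD, n = 6) and were left out of library sizes and tests. The estimated counts of matched transcripts were summed per gene and rounded to whole numbers, which gave 52609 annotated genes. The deposited total per library was 16350923, 13649370 and 9946521 estimated reads with Activin A (replicates 1 to 3), and 14228036, 14992042 and 13567995 without.

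Gene counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by the TMM method, and a robust quasi-likelihood F test compared the group without Activin A with the group with it. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. A log2 fold change is without minus with Activin A, and its standard error is its size divided by the square root of F. CPM values are TMM-normalized and given as mean ± SD over the 3 libraries of a group. Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with adjustment over the 21 lists that had at least 3 tested members and were not set aside for description. The sex-linked list was described without a test. The trophoblast and germ cell lists, with 2 tested members each, were also described only.

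The 24 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names 14 genes of a fixed panel, the 5 largest rises and the 5 largest falls among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, and up to 2 called members per list with the smallest p-values in the main direction of the list. Where rises and falls were equal in number, the direction of camera was taken, or rises in a list not tested. Genes named from such a list show only 1 of its sides. It named 60 genes, and a result among them is not reported here. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-trend on log2(TPM + 1), no low-count filter, a stricter filter of 1 CPM, an average transcript length offset, protein-coding genes only, the replicate number as a block, and the removal of each library in turn. For the lists they were an estimated correlation, fry, the block and RLE scaling. An offset that removes each library's trend on GC content and transcript length (mgcv 1.9.3), the removal of both doubted libraries together, counts of the list members on the removal of each library, 6 further gene lists and a search for shared sequence were added after the data had been seen. In the gene tests that offset also re-centred each library on its mean log2 deviation, so results with the trend removed include a change of scaling.

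The shared-sequence search counted, for each named or mitochondrial gene, the percentage of its 31-base words that also occur in transcripts of other genes (Python 3.11.15, pandas 2.3.3). Replicates were compared with a chi-square statistic over genes with at least 50 reads in a pair. The gene test was tested on simulated counts for the same 15448 genes, with 200 changed genes in 4 fold sizes of 50 genes each. It recovered 18% of the genes changed 1.2-fold, 64% at 1.5-fold, 86% at 2-fold and 88% at 4-fold, and 6 of its 134 calls were unchanged genes. In the simulation both groups had the same spread, and 200 genes changed, against 4505 called in the data. These shares may therefore not carry over to the data. In the simulated list test on 15182 genes, the moved list had an adjusted p of 1.26e-27 and 0 of 50 unmoved lists were called. The simulated genes were drawn independently of one another, so this does not show how often lists of correlated genes would be called. Figures were drawn with matplotlib 3.10.9.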

Results

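Poly(A) RNA of mouse epiblast stem cells was sequenced in 3 libraries with Activin A and 3 without. Activin A is a TGF-beta family ligand that signals through SMAD2 and SMAD3 and maintains these cells in culture. Its inhibitor SB431542, the Wnt secretion inhibitor IWP2 and FGF2 were present in both groups. By its title, the series addresses how Activin A bears on the allocation of the cells to the ectoderm lineage, and the comparison asks which transcripts differed when Activin A was left out. The libraries held 9946521 to 16350923 estimated reads with Activin A and 13567995 to 14992042 without. The design text of the series mentions 2 lines, each in 3 replicates, while the labels of the 6 samples differ only in Activin A, so a difference in cell line between the groups cannot be excluded and would be confounded with Activin A. One library, without Activin A replicate 1, carries a growth factor label that names Activin A, against its title and genotype label. The labels do not say whether the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

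Without Activin A, transcripts of the Nodal/Activin pathway and of the pluripotency factors Pou5f1 and Nanog were lower, and BMP target transcripts were higher. Of 15448 genes tested, 4505 (29.2%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2155 of them higher and 2350 lower without Activin A. Most of these changes were small. Among the called genes, 2862 (63.5%) changed by less than 1.5-fold, 245 were at least 2-fold higher and 504 at least 2-fold lower. The 2 groups' values did not overlap for 42.9% of the tested genes, against 10% by chance for 3 against 3. Libraries separated by group on the first principal component, which held 58.1% of the variance. Every pair of libraries differed by more than sampling noise, so none was treated as deposited a second time, which does not show that they came from separate cultures. The count fell to 2086 with a transcript length offset and to 1559 with limma-trend on TPM. With each library's trend on GC content and length removed, 3931 genes were higher and 2458 lower, or 61.5% higher against 47.8%. That setting also re-centred each library, and the median log2 fold was 0.045, against 0.0012 in the main test. Upper-quartile scaling moved the balance of rises and falls the other way, with 1737 higher and 2702 lower (39.1% higher), so that balance depends on the scaling.

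Nodal pathway transcripts were lower without Activin A. Of 17 tested members of the fixed Nodal/Activin list, 13 fell, 0 rose and 4 did not pass (14 fell adjusted over the list alone), and 1 rose with the GC and length trend removed. Camera gave an adjusted p of 1.02e-24, and an adjusted p of 0.0199 with an estimated correlation. Lefty1, a secreted Nodal antagonist that is itself a Nodal target, went from 160 ± 13.6 CPM with Activin A to 8.44 ± 0.829 CPM without (SD, n = 3 each). This was 18.9-fold lower, a log2 fold change of -4.24 with a standard error of 0.09 (edgeR adjusted p = 2.39e-13). Lefty1 (ENSMUSG00000038793.8) lies on chromosome 1 of GRCm38 at 180935022 to 180938400, and Lefty2, its neighbour, at 180893108 to 180899103. Lefty1 shares 25.7% of its 31-base words with other genes, chiefly Lefty2, so the split of reads between the pair is uncertain. Lefty2 was 4.07-fold lower, at 8.09 ± 1.08 against 1.96 ± 0.102 CPM (edgeR adjusted p = 3.09e-07).

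Tdgf1, the Nodal co-receptor Cripto (ENSMUSG00000032494.12, chromosome 9, 110939603 to 110946158), was 25.7-fold lower without Activin A. Its level was 33.6 ± 1.16 CPM with and 1.30 ± 0.087 CPM without (SD, n = 3 each), with an edgeR adjusted p of 1.57e-12. A pseudogene shares part of the 12.6% of its sequence words found in other genes. Nodal itself (ENSMUSG00000037171.6, chromosome 10, 61417972 to 61425338) was 5.16-fold lower, at 15.8 ± 3.01 against 3.09 ± 0.586 CPM (edgeR adjusted p = 6.07e-08). The inhibitory SMAD gene Smad7 fell by 0.57 on the log2 scale with a standard error of 0.13 (edgeR adjusted p = 0.00386). Its call was lost with the length offset, where the log2 fold was a little smaller at -0.47 and the standard error larger at 0.21 (adjusted p = 0.187), and with limma-trend on log2(TPM + 1), where it was -0.32 with a standard error of 0.15 (adjusted p = 0.238). Folds on that scale are smaller for genes at low TPM.

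Members of the core and primed pluripotency list fell more often than they rose. Of 18 tested, 11 fell, 3 rose and 4 did not pass (12 fell adjusted over the list alone), with a camera adjusted p of 1.00e-10 and an adjusted p of 0.0409 with an estimated correlation. Nanog (ENSMUSG00000012396.12, chromosome 6, 122707489 to 122714633) was 3.94-fold lower, at 235 ± 12.1 CPM with and 59.5 ± 3.85 CPM without Activin A (edgeR adjusted p = 1.15e-11). Pou5f1, which encodes OCT4 (ENSMUSG00000024406.16, chromosome 17, 35506018 to 35510772), was 3.09-fold lower, at 374 ± 28.1 against 121 ± 2.35 CPM (edgeR adjusted p = 4.73e-11). The primed-state genes Otx2 and Fgf5 fell by 0.56 and 0.48 on the log2 scale. Sox2, a factor shared by pluripotent and neural cells, rose 1.33-fold, from 82.3 ± 4.12 to 110 ± 3.43 CPM (edgeR adjusted p = 5.67e-05). It lies within the Sox2ot gene on the same strand, but only 0.89% of its sequence words are shared with other genes, chiefly Sox1. Nanog shares 10.4% of its sequence words with other genes, chiefly a pseudogene. Fgf5 was no longer called with limma-trend on TPM (log2 fold -0.345, adjusted p = 0.0669).

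BMP target transcripts rose. Of 13 tested members of that list, 10 rose, 0 fell and 3 did not pass (11 rose adjusted over the list alone), with a camera adjusted p of 2.22e-13 and an adjusted p of 0.0199 with an estimated correlation. Id3 and Id2 encode inhibitors of basic helix-loop-helix factors. Id3 (ENSMUSG00000007872.3, chromosome 4, 136143497 to 136145755) was 4.45-fold higher without Activin A, at 12.5 ± 0.753 CPM with and 55.6 ± 2.36 CPM without (edgeR adjusted p = 3.51e-11). Id2 was 2.47-fold higher, at 23.1 ± 2.01 against 56.4 ± 1.72 CPM (edgeR adjusted p = 4.40e-09).

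**Figure D1:**
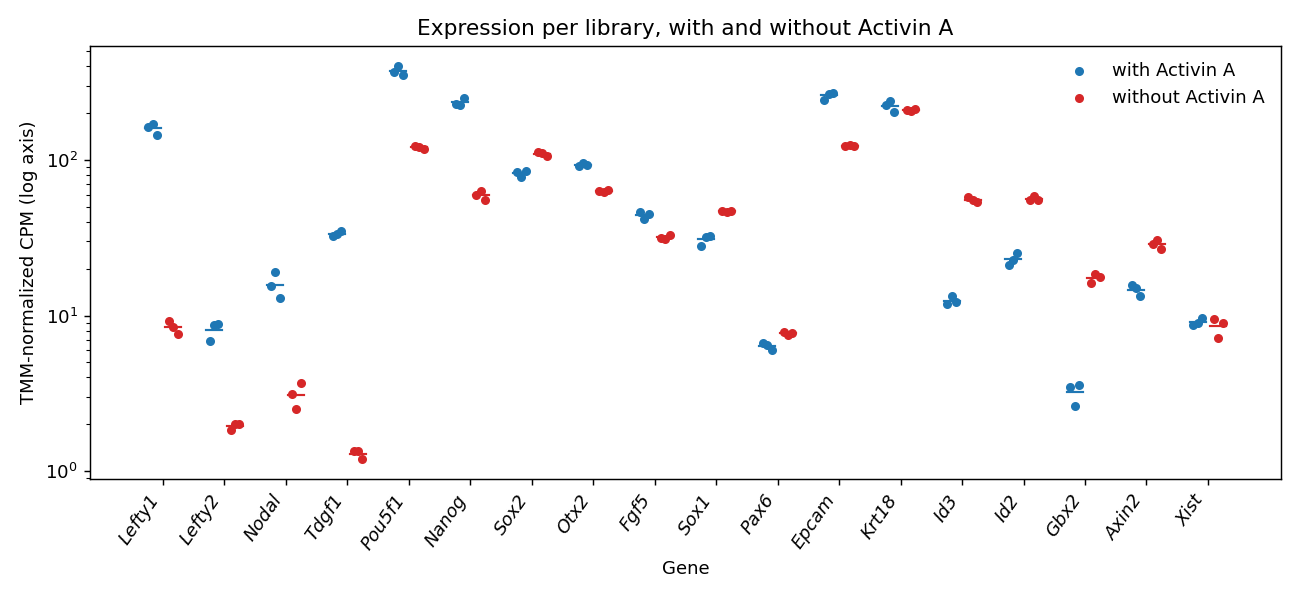
TMM-normalized CPM (log axis) of 18 genes in the 3 libraries with Activin A (blue points) and the 3 without (red points), with short lines at the group means and genes along the horizontal axis. Lefty1, Tdgf1, Nanog and Pou5f1 were lower in every library without Activin A than in any with it, Id3 and Id2 were higher, and the Krt18 and Xist values of the groups overlapped.

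Ectoderm markers moved in both directions. In the neural ectoderm list 6 of 18 tested members rose, 7 fell and 5 did not pass, and camera gave an adjusted p of 0.768. The median log2 fold of that list was 0.05, while its mean was -0.01 and the direction of the test was lower. Sox1, an early neural factor (ENSMUSG00000096014.1, chromosome 8, 12395295 to 12400126), rose 1.52-fold, from 31.01 ± 2.52 to 46.9 ± 0.182 CPM (SD, n = 3 each, edgeR adjusted p = 1.05e-05). It overlaps the Sox1ot gene on its strand, but only 2.06% of its sequence words are shared with other genes, chiefly Kcnj15. Pax6, a neural and eye factor, had 6.36 ± 0.345 and 7.68 ± 0.194 CPM and did not pass (edgeR adjusted p = 0.110), although it passed with the GC and length trend removed (adjusted p = 0.0414). The neural progenitor filament gene Nes and the zinc finger gene Zic5 fell by 0.78 and 0.81 on the log2 scale.

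In the surface ectoderm list 4 of 15 tested members rose, 6 fell and 5 did not pass (camera adjusted p = 0.560). Epcam and Cdh1 encode epithelial adhesion molecules. Epcam was 2.11-fold lower, at 260 ± 14.4 against 123 ± 1.43 CPM (edgeR adjusted p = 1.39e-09), and Cdh1 fell by 0.56 on the log2 scale. Krt18, a simple-epithelium keratin, had 224 ± 18.6 and 211 ± 3.53 CPM and did not pass (edgeR adjusted p = 0.287). It passed when the library with Activin A replicate 3 was left out (adjusted p = 0.00147, fell by 0.15 on the log2 scale), and when both doubted libraries, this one and the library without Activin A replicate 1, were left out (adjusted p = 0.0110). In the neural crest and plate border list 5 of 15 rose and 5 fell (camera adjusted p = 0.994), with 3 rises without the library with Activin A replicate 1 and 3 falls without both doubted libraries. Ngfr, a neurotrophin receptor, was 7.95-fold lower, at 36.6 ± 7.49 against 4.65 ± 0.256 CPM (edgeR adjusted p = 8.31e-08). The highest log2 fold in that list was 1.31.

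Most mesoderm and endoderm markers were too low to be tested. Of 20 primitive streak and mesoderm genes, 8 were tested, of which 1 rose and 5 fell (camera adjusted p = 0.560). The falls numbered 3 without the library with Activin A replicate 1, where 2 rose, and 3 without the library without Activin A replicate 1 or both doubted libraries, and 2 rose with the GC and length trend removed. T, or Brachyury, was not tested, with 2 to 16 reads per library and 0.287 ± 0.159 against 0.612 ± 0.455 CPM, so a difference was not detectable at this depth. Eomes, a streak factor, was called lower at 0.980 ± 0.056 against 0.331 ± 0.045 CPM (edgeR adjusted p = 0.00591), on 4 to 15 reads per library. That call was lost with limma-trend (adjusted p = 0.130), and with DESeq2 (adjusted p = 0.111) and the length offset (adjusted p = 0.0711). In these last settings the log2 fold was -1.56 ± 0.70 and -1.34 ± 0.41 (SE), against -1.53 ± 0.37 in the main test, so the standard error grew. The somite factor gene Tcf15 and the ligand gene Wnt3 fell by 1.43 and 1.15 on the log2 scale. Of 17 endoderm genes 6 were tested, of which 4 rose and 1 fell (camera adjusted p = 0.560). The rises numbered 1 to 3 on leaving out any one library, with 0 falls each time, and were 1 without replicate 1 or 2 of the group with Activin A or replicate 2 of the other, and 2 without replicate 1 or 3 of the other or both doubted libraries. The fall was also lost with the GC and length trend removed. Dab2 rose by 0.34 on the log2 scale. Hhex, at 1.53 ± 0.402 against 2.72 ± 0.451 CPM (edgeR adjusted p = 0.0143), lost its call on leaving out each of 4 single libraries, with adjusted p-values of 0.0771 and 0.0585 without replicates 1 and 2 of the group with Activin A, and of 0.0646 and 0.0620 without replicates 2 and 3 of the other. Its log2 fold was 0.865 ± 0.242 (SE) in the main test and 0.744 to 0.795 in those 4. The call was also lost with DESeq2 (0.855 ± 0.395, adjusted p = 0.123) and the length offset (0.841 ± 0.285, adjusted p = 0.0957), where the fold stayed near and the standard error grew, and with limma-trend (0.404 ± 0.135, adjusted p = 0.113).

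Among naive pluripotency genes 3 of 9 tested members rose and 2 fell (camera adjusted p = 0.560), with 1 fall without replicate 1 of either group. The rises numbered 2 on leaving out any one library except with Activin A replicate 2, and without both doubted libraries. They also numbered 2 with the replicate block or upper-quartile scaling, and 4 with the GC and length trend removed. Gbx2, which also patterns the hindbrain, rose 5.41-fold from 3.24 ± 0.524 to 17.5 ± 1.09 CPM (edgeR adjusted p = 2.79e-09), and Klf4 rose 1.28-fold. Of 9 tested Wnt targets, 3 rose and 2 fell (camera adjusted p = 0.560), with 1 fall without replicate 1 of the group with Activin A or replicate 2 or 3 of the other. Their rises numbered 2 without replicate 1 of the group with Activin A or replicate 2 of the other. There were 4 rises without replicate 3 of the group with Activin A, and with the GC and length trend removed. Axin2, a feedback inhibitor of Wnt signalling, rose 1.94-fold (edgeR adjusted p = 8.58e-07) and Lef1 rose 1.32-fold. In the FGF/ERK list 7 of 17 rose and 7 fell (camera adjusted p = 0.994), with a median log2 fold of -0.10, a mean of -0.01 and a test direction of higher. The rises numbered 4 without the library without Activin A replicate 2. The ERK phosphatase gene Dusp5 rose 2.67-fold (edgeR adjusted p = 2.06e-09) and Phlda1 rose 1.81-fold, while the lowest log2 fold in the FGF/ERK list was -1.55.

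The largest changes under the fixed rule included genes outside these lists. The largest rises were those of Tnfrsf19, a TNF receptor family member (17.2-fold), Frzb, a secreted Wnt antagonist (16.1-fold), the cadherin gene Cdh6 (13.2-fold), the myosin gene Myh7 (6.90-fold) and the imprinted gene Peg10 (6.42-fold). With Activin A, Tnfrsf19 had 0.581 ± 0.132 CPM on 5 to 12 reads per library, and Frzb 0.815 ± 0.305 CPM on 7 to 19 reads. The sizes of these 2 folds are therefore uncertain. Peg10 (ENSMUSG00000092035.8, chromosome 6, 4747306 to 4760517) rose from 77.6 ± 3.86 to 499 ± 7.87 CPM (SD, n = 3 each, edgeR adjusted p = 2.39e-13). Myh7 shares 22.9% of its sequence words with other genes, chiefly Myh6, and overlaps antisense genes. The shared part was 14.8% for Plk1, 14.3% for Fdft1, 11.4% for Krt18 and 10.6% for Zic5. The largest falls were those of Calcr, the calcitonin receptor gene (26.3-fold), Tdgf1, Lefty1, Doc2a (8.70-fold) and Slitrk3 (8.32-fold). Calcr went from 17.7 ± 2.45 to 0.664 ± 0.0742 CPM (edgeR adjusted p = 1.15e-10). Pou5f1, Otx2, Eomes, Pax6, Gbx2, Axin2, Tnfrsf19, Doc2a, Dab2, Lef1, Phlda1, Plk1, Fdft1, Ndrg1, Atf3, Hoxa3, Hoxb2 and Myh7 overlap genes annotated on the opposite strand, with introns counted as part of a gene. Overlap of exons was not examined, and strand use in the counting is not known. Whether their counts hold reads from the opposite strand therefore cannot be told.

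Markers of the fibroblast feeder cells changed in both directions. Of 21 tested, 5 rose, 9 fell and 7 did not pass (camera adjusted p = 0.994). Col3a1, a collagen gene, was 2.31-fold lower at 46.2 ± 1.22 against 19.9 ± 0.358 CPM (edgeR adjusted p = 4.17e-09), and the collagen cross-linking enzyme gene Lox was 2.10-fold lower. Of 14 epithelial-mesenchymal genes 4 rose and 7 fell (camera adjusted p = 0.166), and the tight junction gene Cldn6 was 2.04-fold lower. That list passed without the library with Activin A replicate 3 (camera adjusted p = 0.0390). Of the trophoblast list 2 members were tested, of which 1 rose and 1 fell, and the fall was lost on leaving out any one library, with the replicate block and with the GC and length trend removed. Of the germ cell list 2 were tested and 1 rose, Tfap2c, which is in both lists and rose 1.45-fold. Its call was lost with limma-trend (log2 fold 0.254 ± 0.186 SE, adjusted p = 0.439) and the length offset (0.295 ± 0.199, adjusted p = 0.377), against 0.540 ± 0.098 in the main test, so the fold shrank and the standard error grew.

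Of 15 p53 targets, 8 fell and 1 rose (camera adjusted p = 0.171), with Btg2 and Ccng1 falling by 0.40 and 0.29 on the log2 scale, and 2 rose with the GC and length trend removed. The falls numbered 5 without the library with Activin A replicate 2 and 4 without the library without Activin A replicate 3, and Ccng1 was not called with limma-trend (log2 fold -0.274, adjusted p = 0.136). In the replication and cell cycle list 5 of 19 rose and 1 fell (camera adjusted p = 0.560), including the mitotic kinase genes Plk1 and Aurka, higher by 0.26 and 0.20 on the log2 scale. That list had 8 rises and 3 falls without the library with Activin A replicate 3, 2 rises without replicate 2 of the group without Activin A, and 3 rises without replicate 2 of the group with it or replicate 1 or 3 of the other. It had 8 rises and 2 falls with the GC and length trend removed and 3 rises and 2 falls with upper-quartile scaling. Aurka, at a log2 fold of 0.204 ± 0.051 (SE), was not called without the library without Activin A replicate 2 (0.187 ± 0.064, adjusted p = 0.0548), with limma-trend (0.211 ± 0.074, adjusted p = 0.130) or with the length offset (0.196 ± 0.062, adjusted p = 0.0795), and its fold stayed near while the standard error grew. Of 17 cholesterol synthesis genes 1 rose and 2 fell, Fdft1 and Insig1, by 0.28 and 0.24 on the log2 scale (camera adjusted p = 0.768). The list had 3 rises and 4 falls without the library with Activin A replicate 3, 0 rises without any one library of the other group, 6 rises and 3 falls with the GC and length trend removed, 2 rises without both doubted libraries and 4 falls with upper-quartile scaling. Neither Fdft1 (log2 fold -0.191, adjusted p = 0.143) nor Insig1 (log2 fold -0.186, adjusted p = 0.259) was called with limma-trend. Of 16 glycolysis and hypoxia genes 2 rose and 4 fell (camera adjusted p = 0.560), among them Ndrg1 and Ddit4, lower by 1.88-fold and 1.29-fold. Ndrg1 was not called with limma-trend (log2 fold -0.450 ± 0.144 SE, adjusted p = 0.102) or the length offset (-0.505 ± 0.161, adjusted p = 0.0805), against -0.913 ± 0.063 in the main test, so the fold shrank and the standard error grew. In the stress response list 5 of 15 rose and 5 fell (camera adjusted p = 0.560), with 3 falls without the library without Activin A replicate 2, and Trib3 and Chac1 rose 1.59-fold and 1.49-fold. The lowest log2 fold in the stress response list was -0.76. Of 13 immediate early and heat shock genes 5 rose and 2 fell (camera adjusted p = 0.560), with Fosb and Atf3 higher by 1.38-fold and 1.25-fold, a list median of 0.10, a mean of -0.04 and a test direction of higher. On leaving out 1 library that list had 3 to 5 rises and 1 to 3 falls, with 1 fall without any library but with Activin A replicate 3, and 3 rises without replicate 2 of either group or replicate 3 of the group without Activin A. It had 4 falls without both doubted libraries, and 1 with the GC and length trend removed or the replicate block.

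Of 7 tested Hox genes 2 fell and 0 rose (camera adjusted p = 0.560). Hoxa3 was called lower at 1.24 ± 0.328 against 0.168 ± 0.0874 CPM (edgeR adjusted p = 0.000293) and overlaps several genes on both strands. Its call was lost with the length offset (adjusted p = 0.0596), where the log2 fold stayed near the main -2.85 ± 0.46 (SE) at -2.73 ± 0.79 and the standard error grew, and with limma-trend (-0.357 ± 0.155, adjusted p = 0.203). Hoxb2, on 4 to 14 reads per library (edgeR adjusted p = 0.0233), lost its call on leaving out any one library except with Activin A replicate 3, with adjusted p-values from 0.0528 to 0.112, which left 1 fall in the list. Hoxb2 was also not called with DESeq2 (adjusted p = 0.238), without a low-count filter (adjusted p = 0.0612), with the length offset (adjusted p = 0.0506) or without both doubted libraries (adjusted p = 0.0583). Its log2 fold was -1.23 ± 0.38 (SE) in the main test, -1.26 ± 0.35 with the length offset, where only the adjusted p moved past the threshold, and -1.03 to -1.36 in the other settings that ended the call. Of 13 mitochondrially encoded transcripts 1 fell, mt-Co3 (edgeR adjusted p = 0.0233), and 0 fell adjusted over the list alone (camera adjusted p = 0.768). Its sequence words are 99.9% shared with other genes, and the call was lost without the library with Activin A replicate 3 (adjusted p = 0.206), without both doubted libraries (adjusted p = 0.290), with limma-trend (adjusted p = 0.135) and with the GC and length trend removed (adjusted p = 0.0869). The log2 fold of mt-Co3 was -0.425 ± 0.111 (SE) in the main test and -0.383 ± 0.172, -0.436 ± 0.208, -0.400 ± 0.144 and -0.374 ± 0.128 in these settings, in the same order, so the standard error grew in each. The list had 2 falls without replicate 1 or 2 of the group with Activin A, and 1 rise and 2 falls with the replicate block. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were detected in both groups, and none of the 5 sex-linked genes passed (0 rose and 0 fell), while 2 rose without the library with Activin A replicate 3, and 1 rose without both doubted libraries or with the GC and length trend removed.

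**Figure D2:**
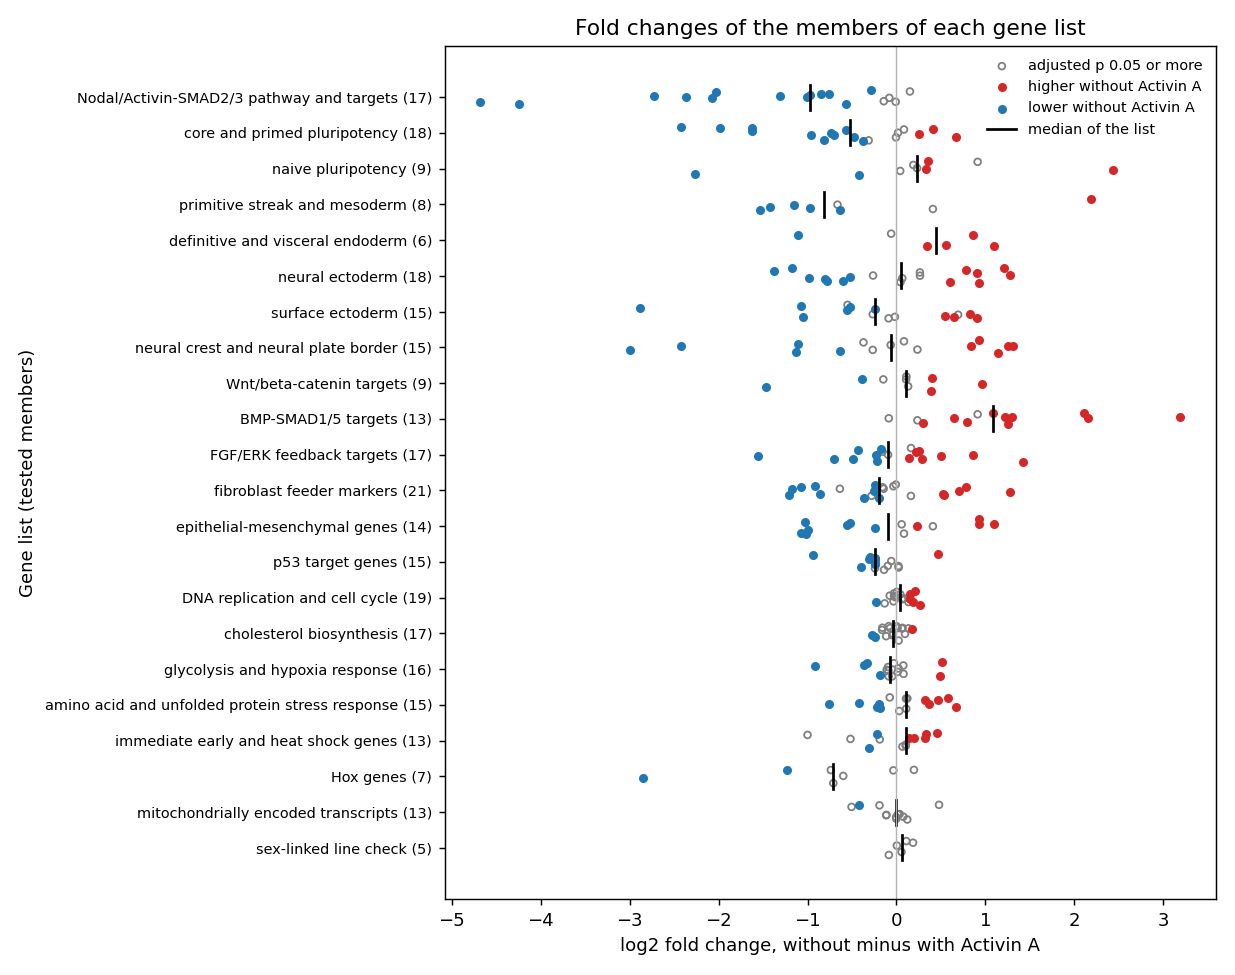
Log2 fold change (without minus with Activin A) of each tested member of the gene lists with at least 3 tested members, one list per row, with filled points for genes past the threshold, open circles for the others and a black line at the list median. Of 17 Nodal/Activin genes 13 fell and 0 rose, and of 13 BMP targets 10 rose and 0 fell, while of 18 neural ectoderm genes 6 rose and 7 fell.

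Libraries with Activin A differed more from one another than those without. The common biological coefficient of variation was 7.47% with and 2.70% without Activin A. The gene test fitted 1 dispersion per gene over both groups, so its p-values pool these unequal spreads. The library with Activin A replicate 3, the shallowest, stood apart on the second principal component. Leaving it out gave 5689 calls, and leaving out any other single library gave 3246 to 3818. With both that library and the library without Activin A replicate 1 left out, 4988 genes were called, the Nodal/Activin list had 13 falls and 0 rises among 17, the core list 12 falls and 3 rises among 18, and the BMP list 9 rises and 0 falls among 12. This removal was chosen after the data had been seen.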

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

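The tests of the title and culture of the library without Activin A replicate 1, of the feeder share and of the source of Xist were chosen only after the results were seen. Reads of Xist, the RNA that coats the inactive X chromosome of female cells, appeared beside Y-linked transcripts in every library. Its mean over the 6 libraries was 8.83 ± 0.859 CPM (SD, n = 6), on 96 to 143 reads per library. The log2 fold of Xist lay 0.115 above the feeder marker median, which does not separate a female share among the feeder cells from other sources. Transcripts with no gene assigned held 0.140% of the reads, at 0.135% ± 0.0044 with and 0.144% ± 0.0051 without Activin A (n = 3 each).

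The first pattern is the number of called genes, 4505, and removal of each library's trend on GC content and length left 6389 calls. That setting also re-centred the libraries and moved the median log2 fold from 0.0012 to 0.045, so added rises may reflect scaling. The falls, which that move works against, still numbered 2458, which argues against such a trend as the whole cause of the falls. Of the 10 splits of the 6 samples into 3 and 3, 1 gave a count as large, the real one, and the highest of the others was 0, but 10 splits are too few for a share under 0.05. For the library without Activin A replicate 1, the lowest chi-square per degree of freedom against a library with Activin A was 17.4 and the highest against its own group 2.16, with 8.02 for the widest pair within a group, which argues against a culture like the 3 with Activin A behind it. An earlier test took the 704 genes that the other 5 libraries called over 2-fold. Of these, 94.9% had this library nearer to the 2 others without Activin A, just short of the 95% set for excluding a wrong title. By the same measure, computed afterwards, 4 of the other 5 libraries also missed that bound (91.7% to 94.8%), so it cannot decide. The chi-square of this library against those 2 was 2.16 and 1.91, and 2.18 between them. This argues against an outside sample that differs from them, while one grown alike stays open. Leaving the library out still gave 3304 calls, 3213 of them main calls, which argues against its title as the whole cause of the count. Both the absence of Activin A and a difference in cell line, which the design text leaves possible, remain open and untested.

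The second pattern is the change of feeder markers in both directions. A different share of feeder cells alone would move markers that only these cells express one way, and at least 5 markers were called in each direction. That count restates the pattern and was known when the test was chosen, so it cannot decide. Whether only feeder cells express these markers was not examined. Col1a1 and Acta2, among the more abundant, rose by 0.54 and 1.28 on the log2 scale while Col3a1 fell by 1.21. Col1a1 and Acta2 were chosen after their values were seen. Acta2 and Tagln, which rose by 0.52, are also in the actin and SRF/YAP list described below, where 14 of 15 tested members rose. A different share of feeder cells stays open. A response of the feeder cells or of the stem cells to Activin A also stays open and was not tested.

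The third pattern is the wider spread with Activin A. With all libraries thinned to the depth of the shallowest, the lowest chi-square per degree of freedom of a pair with Activin A was 3.07 against a highest of 1.85 without, so depth does not account for it. Removal of the GC and length trend lowered the median over the pairs with Activin A from 6.74 to 3.26, which stayed above the highest pair without, 2.16. By this measure the trend carried much of the excess spread, but not all of it. The deviations of the libraries with Activin A from their group had Spearman correlations of 0.29, 0.48 and -0.59 with GC content (replicates 1 to 3). Those without Activin A had 0.03, 0.03 and -0.07. Deviations from a group's own mean are tied to one another, so the trend cannot be assigned to 1 library. The correlations run across genes, which are not independent replicates. What remains may be biological or technical, and no table separates these.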

How the results depend on the processing

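The GC and length offset and the removal of both doubted libraries were chosen only after the results were seen. The main count of 4505 stayed between 3060 and 6389 except with limma-trend on log2(TPM + 1) (1559 genes, 778 higher and 781 lower) and the transcript length offset (2086, 1058 higher and 1028 lower); the cause was not tested. There, 112 and 113 of the main calls had the opposite sign. DESeq2 called 3060 genes, 1495 of them lower, and the cause was not tested. The GC and length offset called 6389, 3931 of them higher, and it also re-centred the libraries. How much of that larger count came from re-centring was not tested. Leaving out 1 library gave 3246 to 5689 genes, 1483 to 2808 higher and 1763 to 2881 lower. The 3 called lists became 11 with fry, which asks whether a list's own genes move and compares them with no others, and 3 to 4 on leaving out 1 library. Replicate numbers did not pair the samples: correlations of same-numbered deviations were -0.02, -0.05 and -0.06, and 0 of 6 samples correlated best with their own number. The replicate block called 4422 genes and 3 lists. Of 1001 values of the 59 tested named genes under the alternatives, 960 kept direction and side of the threshold, 38 lost the call, 3 gained it and 0 reversed. Depth limits genes under about 1 CPM, such as T, Eomes and Hoxb2.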

Other observations

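The 6 gene lists here were chosen after the largest changes had been seen, so members already seen were left out of their tests, and 7 tests were made in this family. Genes of the actin cytoskeleton and of the SRF and YAP pathways were higher without Activin A in 14 of 15 tested members, with 0 lower. The actin crosslinkers Actn1 and Flna rose by 0.86 and 0.53 on the log2 scale, the adhesion gene Vcl by 0.60 and the Hippo kinase gene Lats2 by 0.88, all chosen after their values were seen. Camera gave an adjusted p of 1.25e-12 over the 6 lists, but an adjusted p of 0.0828 with an estimated correlation, so whether leaving out Activin A moves this list as a whole stays open. Feeder fibroblasts also express these genes, and which cells carry the change cannot be told apart in these libraries.

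None of the other 5 lists passed in 1 direction. The camera adjusted p was 0.0873 for imprinted genes (12 rose and 6 fell of 39), 0.0873 for Notch genes (1 rose and 6 fell of 14) and 0.0873 for Hedgehog genes (6 rose and 1 fell of 10). It was 0.106 for retinoic acid genes (4 rose and 6 fell of 15) and 0.182 for midbrain and hindbrain patterning genes (4 rose and 4 fell of 12). Imprinted genes may change more often than other genes of like expression. Of 39, 18 (46.2%) were called, at percentile 95.95 of 10000 random lists matched on expression, whose median was 30.8%. That percentile is not adjusted for the 7 tests and lies close to the 95th, so it is a weak hint.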
